A study of Mus musculus with 28 samples.

How the data were processed

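Whole liver of C57BL/6 mice was profiled by RNA sequencing in 28 libraries. Per the labels the mice were males of 20 to 30 g, RNA was extracted with Trizol, and libraries were made with an Illumina TruSeq kit and sequenced on a HiSeq instrument. The authors deposited 1 table of FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) per gene and library, to 2 decimals, with 1 column per library. The labels name Cuffdiff and the builds mm10 and GRCm38 without versions. The aligner is not given in the sources used here, nor are read totals. Each library's group (genotype, agent, time) was taken from its label, and replicate numbers from the column names, 5 to 7 at 28 days and 1 to 4 at 90 days. The table held 17792 genes, of which 17743 (99.7%) were matched to RefSeq genes of GRCm38.p6 by Entrez number for positions, and 22 had no usable symbol. The table's own test columns were not used here.

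The depth was estimated from the spacing of low FPKM values in 1051 genes with 1 short transcript, where 1 fragment gives a fixed step. Between 69.1% and 81.8% of these values lay within 0.15 of a step from a whole number of steps. The estimate ran from 9.17 to 14.49 M fragments, a ratio of 1.58 between libraries, and at the lowest depth a gene of 1 kb at 1 FPKM held 9.2 fragments. This estimate is approximate and gives no counting interval.

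FPKM values were transformed as log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 libraries were tested, 11213 in all. In R 4.3.3, limma 3.58.1 fitted 8 group means to all 28 libraries, with 20 residual and 4.17 prior degrees of freedom and a variance trend. The 12 comparisons were DEHP against CMC in each genotype and time, knockout against wild type under each agent and time, the genotype by DEHP interaction at each time, the DEHP by time interaction over both genotypes, and the genotype difference over the mean of the 4 strata. Tests were two-sided and genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Means and SDs are of FPKM, and log2 fold changes are fitted values with the pseudocount of 1. Before the data were examined, 38 gene lists were fixed, covering metabolic and stress pathways, sex-biased and zonal genes, and markers of other cell types and tissues. The 34 lists with at least 5 measured members were tested with camera, at a preset correlation between genes of 0.01 and with an estimated correlation, and with fry, adjusted over the lists. Where no fry value is printed, list results are those of camera alone. Members were also adjusted within the list. Some genes stand on more than 1 list, such as Nqo1 and C6, and hepatocytes express part of the adipocyte list.

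Genes named in the text were chosen by a rule fixed at the same time. It takes Pparg in all groups. It takes the 6 highest and 6 lowest log2 fold changes among called genes whose groups do not overlap, with a mean of at least 1 FPKM and a proper symbol. It takes the 3 smallest adjusted p of each of up to 7 lists with at least 2 called members, and the 5 smallest of each interaction. Where a comparison called under 5 genes it takes these and the 5 smallest p, and for marker lists the 2 most abundant members. Members of a described list may be named beyond these. Some genes the rule takes are not reported here. Genes named outside the rule are said to be so.

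The alternatives were a pseudocount of 0.1, no filter and a stricter filter of 5 FPKM, upper quartile scaling, quantile normalization, library weights, the replicate number as a block, a fit of the same time point, a fit of the groups compared, and leaving out each library in turn. Chosen after seeing the data were a pancreas score (the mean log2 value of the exocrine pancreas list) as a covariate, leaving out 5 libraries with pancreas transcripts, leaving out 3 libraries low in endothelial markers, and the block in a fit of 2 groups. The replicate number was checked as a pairing by the correlation of residuals between groups for libraries of the same number. In DEHP against CMC in wild type at 90 days all 4 were above 0.1 (0.262, 0.252, 0.22 and 0.665), and they were -0.137, -0.132, -0.089 and -0.6 once the pancreas score was removed, libraries 4 of both groups holding pancreas transcripts. No other comparison had all of its pairs above 0.1, so block values stand beside that comparison. The fit was tested on simulated data with 200 changed genes of 11213. For 2-fold changes it recovered 97.0% in the DEHP comparison at 28 days, 91.0% at 90 days, 76.1% and 86.6% in the interactions at 28 and 90 days and 98.5% in the mean genotype difference, with 5 to 13 false calls. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the table and drew the plots.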

Results

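RNA from whole liver of mice was sequenced in 28 libraries. The labels divide them into 8 groups by genotype, agent and time. Knockout mice lacked Pparg in macrophages according to the labels, and wild-type mice served beside them. Mice received di(2-ethylhexyl) phthalate (DEHP, a plasticizer whose metabolite activates the receptor PPARalpha in rodent liver) at 625 mg/kg by gavage, or the vehicle 0.5% carboxymethyl cellulose (CMC), for 28 or 90 days. Each group held 3 libraries at 28 days and 4 at 90 days, named here by WT or KO, agent and replicate number. The labels speak of 12 mice per group and do not say which mice gave which library, so every p-value measures the spread between these libraries. The deposited values are FPKM per gene, with summed FPKM from 514267 to 547757 per library at 28 days and from 573429 to 647703 at 90 days. Read totals were not given. The step between the lowest values of 1051 short genes put the depth at about 9.17 to 14.49 M fragments per library (M, mega), an approximate figure. Between 9738 and 10641 genes per library reached 1 FPKM.

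Pparg, the nuclear receptor gene deleted in macrophages of the knockout, was low in whole liver in all 8 groups. Pparg (Entrez 19016, chromosome 6, 115360879 to 115490404) on GRCm38 had 2.82 ± 0.11 FPKM (SD, n = 3) in wild type under CMC and 6.17 ± 1.69 under DEHP at 28 days. The knockout had 2.48 ± 1.17 and 5.12 ± 0.411 FPKM at that time (SD, n = 3). At 90 days the means were 3.34 ± 2.04 and 4.88 ± 0.583 FPKM in wild type, and 2.36 ± 0.876 and 5.32 ± 0.981 FPKM in the knockout (SD, n = 4). Pparg was higher under DEHP in wild type at 28 days (log2 fold change of 0.88, adjusted p = 0.0362), in the knockout at 28 days (0.86, adjusted p = 0.0341) and in the knockout at 90 days (0.93, adjusted p = 0.0272). In wild type at 90 days the difference of 0.56 did not pass (adjusted p = 0.197). No knockout against wild-type difference in Pparg passed: the log2 values were -0.18 and -0.20 at 28 days and -0.27 and 0.10 at 90 days under CMC and DEHP. A gene total over the whole organ cannot show the state of the gene in macrophages. The 3 DEHP calls lay near the threshold. Leaving out 1 library ended the call in 5 of 6 omissions in wild type at 28 days (all but WT DEHP replicate 5), in 5 of 6 in the knockout at 28 days (all but KO CMC replicate 5) and in 6 of 8 in the knockout at 90 days (all but KO CMC replicate 4 and KO DEHP replicate 1).

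Lyz2, a lysozyme gene of macrophages and neutrophils, separated the genotypes in every group. Lyz2 (Entrez 17105, chromosome 10, 117277541 to 117282272) had 86.9 ± 35.1 and 67.3 ± 24.95 FPKM in wild type under CMC and DEHP at 28 days (SD, n = 3), against 1.51 ± 0.235 and 1.89 ± 1.02 in the knockout. At 90 days it had 85.3 ± 12.9 and 57.2 ± 6.32 FPKM in wild type (SD, n = 4), against 1.62 ± 0.482 and 1.25 ± 0.454 in the knockout. Transcripts of the sex chromosomes separated the time points. Xist, the RNA that coats the inactive X chromosome in female cells, lay between 26.7 and 41 FPKM in the 12 libraries of 28 days and between 0 and 0.02 FPKM in the 16 libraries of 90 days. The 4 Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were listed at 0 in 12 of 12 libraries of 28 days and above 0 in 16 of 16 libraries of 90 days, where Ddx3y lay between 6.27 and 12.96 FPKM. The labels give male mice for every library. Sex as read from these transcripts is thus tied to time, and no comparison of 28 with 90 days can separate them.

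**Figure D1:**
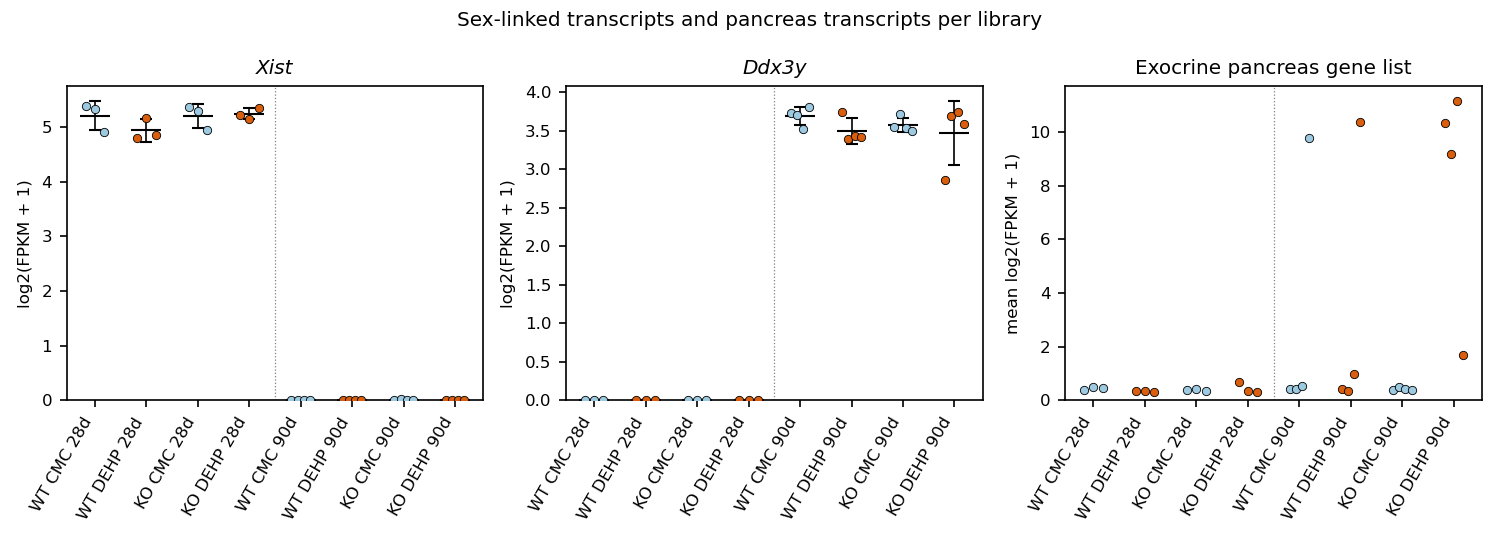
Xist and Ddx3y (log2 of FPKM + 1) and the mean log2 value of the exocrine pancreas genes, 1 point per library, by group. Xist is present in the 12 libraries of 28 days and Ddx3y in the 16 libraries of 90 days, and 5 libraries of 90 days stand apart in pancreas transcripts.

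The first comparison asked how the liver of wild-type mice differed after 28 days of DEHP. Under DEHP 40 of 47 fatty acid oxidation and PPARalpha target genes (for short, fatty acid oxidation genes) were higher, and 11 of 22 female-biased liver genes were lower. Ehhadh (Entrez 74147, chromosome 16, 21761285 to 21787834), a bifunctional enzyme of peroxisomal fatty acid oxidation, had 3617 ± 1485 FPKM under DEHP and 96.3 ± 23.97 under CMC (SD, n = 3), a log2 fold change of 5.15, SE 0.438, adjusted p = 8.3e-09. Cyp3a41a (Entrez 53973, chromosome 5, 145694049 to 145720136), a cytochrome P450 gene that is female-biased in mouse liver, fell to 13.1 ± 18.3 against 812 ± 93.9 FPKM (-6.89, adjusted p = 3.1e-08). Of 11213 genes tested, 1158 were higher and 692 lower. In 1729 of the 1850 called genes the libraries of the groups did not overlap, an arrangement that chance gives to 10% of unselected genes with 3 libraries against 3. Called genes were chosen for their difference, so such counts describe them and test nothing. Outside the fixed lists, Ly6d, a cell surface protein gene, stood among the 6 highest (122 ± 25.5 against 7.68 ± 11.7 FPKM).

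Of 47 measured fatty acid oxidation and PPARalpha target genes, 40 rose, 0 fell and 7 did not pass (42 higher and 0 lower when adjusted within the list). Their median log2 fold change was 1.42 (higher by camera with adjusted p = 4.0e-39, and adjusted p = 0.0699 with an estimated correlation). Cyp4a31 (Entrez 666168, chromosome 4, 115563627 to 115579015) and Cyp4a32, fatty acid omega-hydroxylases, rose by 5.08 and 3.08 on the log2 scale, although reads may be shared within the Cyp4a family. Of 25 sterol synthesis genes, 16 rose and 0 fell, led by Acat2 (1.88, adjusted p = 7.3e-06), Tm7sf2 (0.64, adjusted p = 3.7e-04) and Sc5d (1.04, adjusted p = 6.7e-04). The list gave 20 higher and 0 lower when adjusted within the list (higher by camera with adjusted p = 1.9e-09, and adjusted p = 0.342 with an estimated correlation). Of 23 fatty acid and triglyceride synthesis genes, 16 rose and 2 fell (16 higher and 2 lower when adjusted within the list). Camera put the list higher (adjusted p = 1.4e-06, and adjusted p = 0.342 with an estimated correlation). Me1, the cytosolic malic enzyme, rose from 45.2 ± 9.12 to 297 ± 106 FPKM, and Acsl5 and Fads2 rose by 1.38 and 1.62. The members that fell were Pklr, the liver pyruvate kinase (-1.62), and Dgat2, which makes triglycerides (-0.62). Of 13 PPARgamma lipid uptake and storage genes, 8 rose and 0 fell (8 higher and 0 lower when adjusted within the list). By camera the list lay higher (adjusted p = 1.4e-06, and adjusted p = 0.192 with an estimated correlation). Mogat1, a monoacylglycerol acyltransferase, had 23.00 ± 3.15 FPKM under DEHP and 0.080 ± 0.010 under CMC. Lpl, Pltp and Cd36 rose by 4.23, 2.75 and 2.44 on the log2 scale.

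Among 38 xenobiotic metabolism genes induced through CAR and PXR, 9 rose and 4 fell (10 higher and 4 lower when adjusted within the list). As a list these genes lay higher by camera (adjusted p = 0.00492, and adjusted p = 0.631 with an estimated correlation). Aldh1a7 and the exporter gene Abcc4 rose by 1.61 and 1.81, whereas Cyp2c37, Cyp2c54, Cyp2c50 and the transporter gene Slco1a4 fell by 2.39, 1.73, 0.90 and 2.0. Of 21 oxidative stress genes induced through NRF2, 10 rose and 0 fell (11 higher and 0 lower when adjusted within the list), with Taldo1 at 0.92, Pgd at 1.21 and Gsta1 at 4.0. The list lay higher by camera (adjusted p = 1.5e-07, and adjusted p = 0.21 with an estimated correlation). Interferon-stimulated genes were lower: of 27, 0 rose and 11 fell (0 higher and 12 lower when adjusted within the list; lower by camera with adjusted p = 1.1e-06, and adjusted p = 0.342 with an estimated correlation). Isg15, a ubiquitin-like antiviral protein gene, had 10.7 ± 3.65 FPKM under DEHP and 28.7 ± 4.99 under CMC, and Ifit1 and Ifit3 fell by 1.30 and 1.01. Of 22 female-biased genes, 3 rose and 11 fell (3 higher and 13 lower when adjusted within the list; lower by camera with adjusted p = 5.0e-11, and adjusted p = 0.0407 with an estimated correlation). Cyp3a41a, Cyp2c69, Cyp3a44, Cyp3a41b and A1bg fell by 6.89, 5.51, 4.86, 2.78 and 4.54, with reads possibly shared within Cyp3a and Cyp2c. Male-biased genes went both ways, 4 higher and 5 lower of 18 (4 higher and 7 lower when adjusted within the list; not passing by camera, adjusted p = 0.331). Cyp4a12a had 153 ± 42.3 FPKM under DEHP and 0.273 ± 0.205 under CMC, while Cyp4a12b was listed at 0 in every CMC library and had 79.8 ± 24.5 FPKM under DEHP. Serpina1e, a protease inhibitor gene of a family with shared reads, had 1.43 ± 0.564 FPKM under DEHP and 462 ± 143 under CMC. Of 14 periportal hepatocyte genes, 0 rose and 6 fell, among them Cps1 of the urea cycle at -0.64 (0 higher and 10 lower when adjusted within the list). Tested as a list, these genes lay lower by camera (adjusted p = 1.1e-05, and adjusted p = 0.0528 with an estimated correlation). Of 14 Kupffer cell, 15 endothelial, 7 bile duct and 5 erythroid marker genes, 0 passed. Stellate cell and matrix genes had 0 higher and 3 lower of 14, Dcn, Des and Ecm1 (lower by camera with adjusted p = 0.00918, and adjusted p = 0.653 with an estimated correlation). Of 18 clock genes, Dbp rose, and Cry1, Npas2 and Hlf fell (1 higher and 3 lower when adjusted within the list; not passing by camera, adjusted p = 0.375), at hours of collection that were not given.

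The calls came from limma, and leaving out any 1 library kept the call of 30 of the 31 genes named by rule, Pparg excepted. The share of called genes that were higher was 62.6% as deposited and 50.4% after upper quartile scaling. A fit of these 2 groups alone called 926 genes and library weights 3184.

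The same question was put to the knockout at 28 days. Under DEHP 42 of 47 fatty acid oxidation genes were higher. Acaa1a, the peroxisomal thiolase, had 303 ± 46.5 FPKM under DEHP and 91.3 ± 19.98 under CMC (SD, n = 3; log2 fold change of 1.73, SE 0.144, adjusted p = 4.4e-09). Fabp3, a fatty acid binding protein gene, and Ly6d were among the 6 highest, at 32.5 ± 4.95 against 0.107 ± 0.0924 FPKM and 114 ± 12.5 against 1.28 ± 1.17 FPKM. In all, 1301 genes were higher and 983 lower, and 2243 of the 2284 did not overlap between groups (10% of unselected genes by chance).

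Of 47 fatty acid oxidation and PPARalpha target genes, 42 rose, 0 fell and 5 did not pass (42 higher and 0 lower when adjusted within the list; median 1.64). As a whole the list lay higher by camera (adjusted p = 1.9e-40, and adjusted p = 0.0931 with an estimated correlation). Cyp4a31 rose by 5.20. Of 25 sterol synthesis genes, 18 rose and 0 fell, with Acat2 at 1.79, Sc5d at 1.14 and Pmvk at 1.55 (20 higher and 0 lower when adjusted within the list). Camera ranked the list higher (adjusted p = 3.2e-09, and adjusted p = 0.351 with an estimated correlation). Fatty acid and triglyceride synthesis genes had 14 higher and 3 lower of 23 (16 higher and 3 lower when adjusted within the list). Over its members the list lay higher by camera (adjusted p = 3.3e-06, and adjusted p = 0.351 with an estimated correlation). Me1 and Acsl5 rose by 2.87 and 1.34, and Pklr, Dgat2 and Lpin1 fell by 1.90, 0.53 and 0.87. PPARgamma lipid storage genes had 8 higher and 1 lower of 13 (8 higher and 2 lower when adjusted within the list), with Mogat1 at 4.30 and Lpl at 4.11, and with Plin4, a lipid droplet protein gene, at -0.77. Camera put the list higher (adjusted p = 1.4e-05, and adjusted p = 0.247 with an estimated correlation). Of 21 NRF2 genes, 14 rose and 0 fell (14 higher and 0 lower when adjusted within the list; higher by camera with adjusted p = 1.4e-10, and adjusted p = 0.1 with an estimated correlation). Ftl1, the ferritin light chain, had 8548 ± 266 FPKM under DEHP and 3504 ± 81.6 under CMC, and Gsta1 and Taldo1 rose by 4.95 and 0.89. CAR and PXR genes had 15 higher and 6 lower of 38 (18 higher and 6 lower when adjusted within the list), led by Aldh1a7 at 1.88, Abcc4 at 2.06 and Aldh1a1 at 1.88, with Cyp2c37, Cyp2c54, Cyp2c50, Slco1a4, Sult1d1 and Ugt2b36 lower. By camera the list lay higher (adjusted p = 4.9e-04, and adjusted p = 0.506 with an estimated correlation).

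Interferon-stimulated genes had 0 higher and 12 lower of 27 (0 higher and 16 lower when adjusted within the list), with Ifit1, Rsad2 and Isg15 at log2 -1.5, -1.19 and -1.26. As a list these genes lay lower by camera (adjusted p = 1.2e-06, and adjusted p = 0.351 with an estimated correlation). Female-biased genes had 2 higher and 11 lower of 22 (3 higher and 12 lower when adjusted within the list; lower by camera with adjusted p = 1.7e-06, and adjusted p = 0.1 with an estimated correlation). Cyp3a41a had 3.31 ± 4.23 FPKM under DEHP and 334 ± 30.1 under CMC, and Sult3a1, a sulfotransferase gene, had 14.96 ± 7.09 FPKM under DEHP and 119 ± 27.7 under CMC. Male-biased genes had 4 higher and 5 lower of 18 (4 higher and 6 lower when adjusted within the list; not passing by camera, adjusted p = 0.851). Cyp4a12a and Cyp4a12b rose to 168 ± 31.8 and 74.02 ± 14.8 FPKM, and Serpina1e and the organic anion transporter Slco1a1 fell by 6.73 and 4.48. Of 14 periportal genes, 0 rose and 9 fell (0 higher and 13 lower when adjusted within the list; lower by camera with adjusted p = 2.8e-08, and adjusted p = 0.0137 with an estimated correlation). Sds, Hal and Ass1, enzymes of amino acid breakdown and the urea cycle, fell by 1.33, 1.38 and 1.12. Of 19 proliferation genes, 5 rose, all of DNA replication: Mcm2, Mcm4, Mcm5, Mcm6 and Cdt1 (6 higher and 1 lower when adjusted within the list; not passing by camera, adjusted p = 0.226). Of 18 clock genes, Dbp and Per3 rose, and Arntl, Cry1, Npas2, Nfil3 and Hlf fell (2 higher and 6 lower when adjusted within the list; not passing by camera, adjusted p = 0.451). Kupffer cell and endothelial markers had 0 calls among 14 and 15 genes. Leaving out any 1 library kept the call of 29 of the 30 genes named by rule, Pparg excepted. The higher share was 56.96% as deposited and 45.8% after upper quartile scaling.

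Whether the knockout responded to DEHP differently at 28 days was tested by the genotype by DEHP interaction. It called 2 female-biased Cyp3a genes, both with smaller falls in the knockout. Cyp3a41b went from 6.33 ± 1.25 to 0.0633 ± 0.11 FPKM in wild type and from 1.39 ± 0.515 to 0.0533 ± 0.0924 in the knockout (SD, n = 3), a log2 difference of 1.61 (SE 0.184, adjusted p = 6.3e-05). Cyp3a16 gave 2.30 (SE 0.406, adjusted p = 0.0428). Both started lower in the knockout under CMC (log2 -1.63 and -2.42), by about the size of the interaction. Cyp3a41b ended near the floor in both genotypes, so a changed response is not shown. Reads may be shared within this family. Next came Synpo, Ctsf and Fam98c (log2 0.98, -0.48 and -0.76), which did not pass. The female-biased list had 2 higher and 0 lower of 22 (3 and 0 when adjusted within the list). It lay higher by camera (adjusted p = 1.0e-06, 0.122 with an estimated correlation and 0.337 by fry). In limma 335 genes had an unadjusted p under 0.05. Of the genes called in wild type, 905 of the 1158 higher and 525 of the 692 lower were called the same way in the knockout, where independent lists would share 134 and 60.7, and 0 were called in opposite directions. Across the 11213 genes the log2 fold changes of the genotypes correlated with Pearson's r of 0.883, genes being no independent replicates. The call of Cyp3a16 was lost without KO DEHP replicates 5, 6 or 7, WT CMC replicates 5 or 6, or WT DEHP replicates 5 or 7, and both calls were lost with a pseudocount of 0.1. The stricter filter and the fit of the same time point called 0, and other settings named below 1 each.

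After 90 days of DEHP, 35 of 47 fatty acid oxidation genes were higher in wild-type liver and 7 of 22 acute phase genes were lower. Cyp4a14 (Entrez 13119, chromosome 4, 115486200 to 115496158), a fatty acid omega-hydroxylase, had 1638 ± 689 FPKM under DEHP and 7.27 ± 7.96 under CMC (SD, n = 4), a log2 fold change of 8.23, SE 0.622, adjusted p = 8.1e-09. Ehhadh had 1173 ± 672 FPKM under DEHP and 48.6 ± 10.3 under CMC (4.45, adjusted p = 4.7e-08), and the acyl-CoA thioesterase gene Acot1 had 95.8 ± 84.7 FPKM under DEHP and 7.33 ± 4.32 under CMC (3.37, adjusted p = 6.0e-04). Serpina12, the adipokine vaspin, and Apoa4, an apolipoprotein gene, had 2.43 ± 1.77 against 18.2 ± 2.08 FPKM and 19.4 ± 9.54 against 93.6 ± 26.6 FPKM. Of 762 called genes, 556 were higher and 206 lower. In 621 the groups did not overlap, which chance gives to 1 in 35 unselected genes with 4 libraries against 4. Among the 6 lowest were also Tff3, Enho, Slc22a7 and Dnajc12, at log2 -2.83, -2.01, -1.99 and -1.77.

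Of 47 fatty acid oxidation and PPARalpha target genes, 35 rose, 0 fell and 12 did not pass (39 higher and 0 lower when adjusted within the list; median 0.83). The list lay higher by camera (adjusted p = 1.4e-41, and adjusted p = 0.165 with an estimated correlation). Cyp4a10 and Cyp4a31 rose by 6.06 and 4.58, with reads possibly shared within Cyp4a. Peroxisome genes outside beta-oxidation had 5 higher and 0 lower of 24 (7 and 0 when adjusted within the list). Tested as a list, these genes lay higher by camera (adjusted p = 2.7e-04, and 0.444 with an estimated correlation). Hacl1, of alpha-oxidation, Cat, the catalase gene, and Gnpat, of ether lipid synthesis, rose by 0.70, 0.37 and 0.35. Sterol synthesis genes had 10 higher and 0 lower of 25 (20 higher and 0 lower when adjusted within the list), with Acat2 at 0.99, Tm7sf2 at 0.59 and Fdft1, squalene synthase, at 1.06. As a whole the list lay higher by camera (adjusted p = 4.6e-12, and 0.444 with an estimated correlation). Fatty acid synthesis genes had 4 higher and 1 lower of 23 (10 higher and 2 lower when adjusted within the list), with Elovl5 at 1.13, Me1 at 1.22 and Acsl5 at 0.68. Camera ranked the list higher (adjusted p = 0.00866, and adjusted p = 0.638 with an estimated correlation). This list did not pass after quantile normalization (adjusted p = 0.0579). PPARgamma lipid storage genes had 5 higher and 0 lower of 13 (5 higher and 0 lower when adjusted within the list). Over its members the list lay higher by camera (adjusted p = 3.4e-08, and 0.165 with an estimated correlation). Cidea, a lipid droplet protein gene, had 10.5 ± 5.79 FPKM under DEHP and 0.223 ± 0.298 under CMC. CAR and PXR genes had 8 higher and 1 lower of 38 (11 higher and 2 lower when adjusted within the list), with Gstm4 at 1.33, Aldh1a1 at 0.87 and Gstt1 at 0.53, and Slco1a4 at -1.0. Camera put the list higher (adjusted p = 2.0e-05, and adjusted p = 0.444 with an estimated correlation). NRF2 genes had 8 higher and 0 lower of 21 (12 higher and 0 lower when adjusted within the list), with Nqo1 at 1.14, Ephx1 at 0.96 and Tkt at 0.53. By camera the list lay higher (adjusted p = 4.4e-05, and 0.444 with an estimated correlation). Beside these groups, the pancreas list had a median of 0.27, the adipocyte list 0.37 and the endothelial list -0.20, with 0, 0 and 0 calls. With 0 calls as well, monocyte and macrophage markers had a median of -0.37 (lower by camera, adjusted p = 0.0187, and 0.638 with an estimated correlation). Stellate cell and matrix genes had 0 calls and a median of -0.30 (lower by camera, adjusted p = 0.0177, and 0.638 with an estimated correlation).

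Acute phase genes had 0 higher and 7 lower of 22 (0 and 8 when adjusted within the list). They lay lower by camera (adjusted p = 4.3e-08, and 0.444 with an estimated correlation). Saa3 had 4.38 ± 0.912 FPKM under DEHP and 72.8 ± 88.1 under CMC, Steap4 had 43.1 ± 22.2 FPKM under DEHP and 143 ± 74.4 under CMC and Cp, ceruloplasmin, had 211 ± 18.5 FPKM under DEHP and 341 ± 89.3 under CMC. The mean log2 value of this list ranged from 6.73 to 9.43 among the 4 CMC libraries. Kupffer cell markers had 0 calls of 14 with a median of -0.36 (lower by camera, adjusted p = 0.00259, and 0.638 with an estimated correlation). Their most abundant members Clec4f and C1qb gave -0.44 and -0.44, neither passing. Female-biased genes, lower under CMC than at 28 days, had 0 higher and 0 lower of 22 (2 and 0 adjusted within the list). Male-biased genes had 2 higher and 3 lower of 18 (2 higher and 7 lower when adjusted within the list; not passing by camera, adjusted p = 0.102), with Cyp4a12a and Cyp4a12b at 1.73 and 2.16. With the replicate block this list passed as lower (adjusted p = 0.0316). Periportal genes had 2 higher and 0 lower of 14 (2 higher and 2 lower when adjusted within the list), with a median of -0.036 and a mean of 0.028. Residuals of same-numbered libraries correlated by 0.22 to 0.665, but by -0.6 to -0.089 once the pancreas score was removed, and the same-numbered library was the closest for replicate 4 alone. The replicate number as a block gave 756 genes in place of 762. In a fit of these groups alone the block gave 298 genes against 304 without it. The calls of Fdft1, Cp, Saa3, Steap4, Cat and Gnpat were lost in at least 1 omission, Fdft1 without WT DEHP replicate 4, Cp without WT CMC replicate 2, Saa3 without WT CMC replicate 1, Steap4 without that library or without WT DEHP replicate 4, Cat in 5 and Gnpat in 6 of 8 omissions. The count was 379 without WT DEHP replicate 4, 474 without WT CMC replicate 2, 507 without WT DEHP replicate 3 and 484 without the 5 libraries with pancreas transcripts, 429 of them shared. The higher share was 72.97% as deposited, 60.5% after upper quartile scaling and 60.98% after quantile normalization.

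In the knockout at 90 days, 31 of 47 fatty acid oxidation genes were higher under DEHP, and 3 of the 4 DEHP libraries held exocrine pancreas transcripts. Cyp4a14 had 1069.5 ± 426 FPKM under DEHP and 0.775 ± 0.516 under CMC (SD, n = 4; log2 fold change of 9.20, SE 0.622, adjusted p = 7.4e-10). Cd36, a fatty acid uptake receptor gene, had 49.5 ± 10.3 FPKM under DEHP and 5.61 ± 1.04 under CMC (2.92, adjusted p = 2.5e-08). Serpina12 and Enho had 2.15 ± 1.84 against 27.6 ± 5.06 FPKM and 5.85 ± 2.65 against 27.9 ± 5.85 FPKM. Of 633 called genes, 501 were higher and 132 lower, and 539 did not overlap between groups (1 in 35 unselected genes by chance). The pancreas list had 12 higher of 13 (13 higher and 0 lower when adjusted within the list; higher by camera with adjusted p = 4.1e-11, and adjusted p = 0.457 with an estimated correlation). Ctrb1, Clps, Prss2 and Amy2a3, digestive enzyme and cofactor genes of the pancreas, were listed at 0 in every CMC library and had 3466 ± 3251, 1343 ± 1389.6, 1662 ± 1651 and 8484 ± 8731 FPKM under DEHP. Cela2a, an elastase gene, had 3092 ± 2912 FPKM under DEHP and 0.505 ± 0.596 under CMC. The adipocyte list had 4 higher of 6 (5 higher and 0 lower when adjusted within the list; higher by camera with adjusted p = 5.9e-05, and adjusted p = 0.224 with an estimated correlation). The plasma cell list had 3 of 4. The endothelial list had a median of -0.34 and 0 calls of 15, with KO DEHP replicate 4 low in these markers. As a list these genes lay lower by camera (adjusted p = 0.00206, and adjusted p = 0.67 with an estimated correlation). Kupffer cell markers had 1 call of 14, C6, lower (lower by camera with adjusted p = 0.0369, and adjusted p = 0.67 with an estimated correlation). They did not pass after upper quartile scaling, after quantile normalization or with the pancreas score as a covariate (adjusted p = 0.104, 0.101 and 0.877).

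Beside these markers, 31 of 47 fatty acid oxidation and PPARalpha target genes rose and 0 fell (35 higher and 1 lower when adjusted within the list; median 0.64), with Cyp4a10 at 7.61 and Cyp4a31 at 4.16. The list lay higher by camera (adjusted p = 1.1e-32, and adjusted p = 0.19 with an estimated correlation). PPARgamma lipid storage genes had 7 higher and 0 lower of 13 (11 higher and 0 lower when adjusted within the list), led by Mogat1 at 2.56, Cd36 and Lpl at 2.01. Tested as a list, these genes lay higher by camera (adjusted p = 3.0e-13, and adjusted p = 0.0484 with an estimated correlation). Of the others, Cfd at 3.76 and Adipoq at 1.69 are also on the adipocyte list. CAR and PXR genes had 10 higher and 0 lower of 38 (14 higher and 1 lower when adjusted within the list), with Cyp2c38 at 1.73, Ugt1a1, the bilirubin conjugating enzyme, at 0.70 and Abcc3 at 1.34. As a whole the list lay higher by camera (adjusted p = 2.6e-05, and adjusted p = 0.47 with an estimated correlation). Sterol synthesis genes had 5 higher and 0 lower of 25 (13 higher and 0 lower when adjusted within the list), with Acat2 and Tm7sf2 at 0.92 and 0.55. Camera ranked the list higher (adjusted p = 1.3e-06, and adjusted p = 0.527 with an estimated correlation). Fatty acid synthesis genes had 3 higher and 2 lower of 23 (7 higher and 3 lower when adjusted within the list; not passing by camera, adjusted p = 0.647), with Elovl5 at 1.21, Pklr at -1.56 and Lpin1 at -1.29. NRF2 genes had 2 higher and 0 lower of 21 (4 higher and 0 lower when adjusted within the list; higher by camera with adjusted p = 0.00763, and adjusted p = 0.642 with an estimated correlation). Female-biased genes had 3 higher, Abcd2, Cyp2a22 and Tox, and 0 lower of 22 (6 higher and 0 lower when adjusted within the list; not passing by camera, adjusted p = 0.0515). They passed as a list, higher, after upper quartile scaling and quantile normalization (adjusted p = 0.00616 and 0.016). Male-biased genes had 2 higher and 5 lower of 18 (2 higher and 9 lower when adjusted within the list), with Cyp4a12a and Cyp4a12b at 1.5 and 2.05, and Sdr9c7 and Serpina1e at -1.99 and -1.68. Over its members the list lay lower by camera (adjusted p = 2.6e-05, and adjusted p = 0.47 with an estimated correlation). Apoa4 and Slc22a7 were lower, at -1.89 and -1.58. Of 22 acute phase genes, 1 rose and 0 fell (0 higher and 0 lower when adjusted within the list; lower by camera with adjusted p = 0.0119, and adjusted p = 0.67 with an estimated correlation). This list did not pass with the pancreas score as a covariate (adjusted p = 0.92) or after upper quartile scaling or quantile normalization (adjusted p = 0.118 and 0.174), and it did with the replicate block (adjusted p = 0.0102). With that covariate 57 genes were called, 55 of them among the 633, and without the 5 libraries with pancreas transcripts 272 were called, 207 of them among the 633. That leaves 1 library under DEHP, which was assumed to vary like the others. The calls of Amy2a3, Ctrb1, Clps, Cela2a, Prss2 and Acat2 were lost without KO DEHP replicate 3, and that of Prss2 in 7 of 8 omissions. A fit of these 2 groups alone called 361. The count was 253 without that library, 285 without KO CMC replicate 1, 380 without KO CMC replicate 3 and 411 without KO DEHP replicate 4, and the higher share of 79.1% became 57.1% after upper quartile scaling and 49.1% after quantile normalization.

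**Figure D2:**
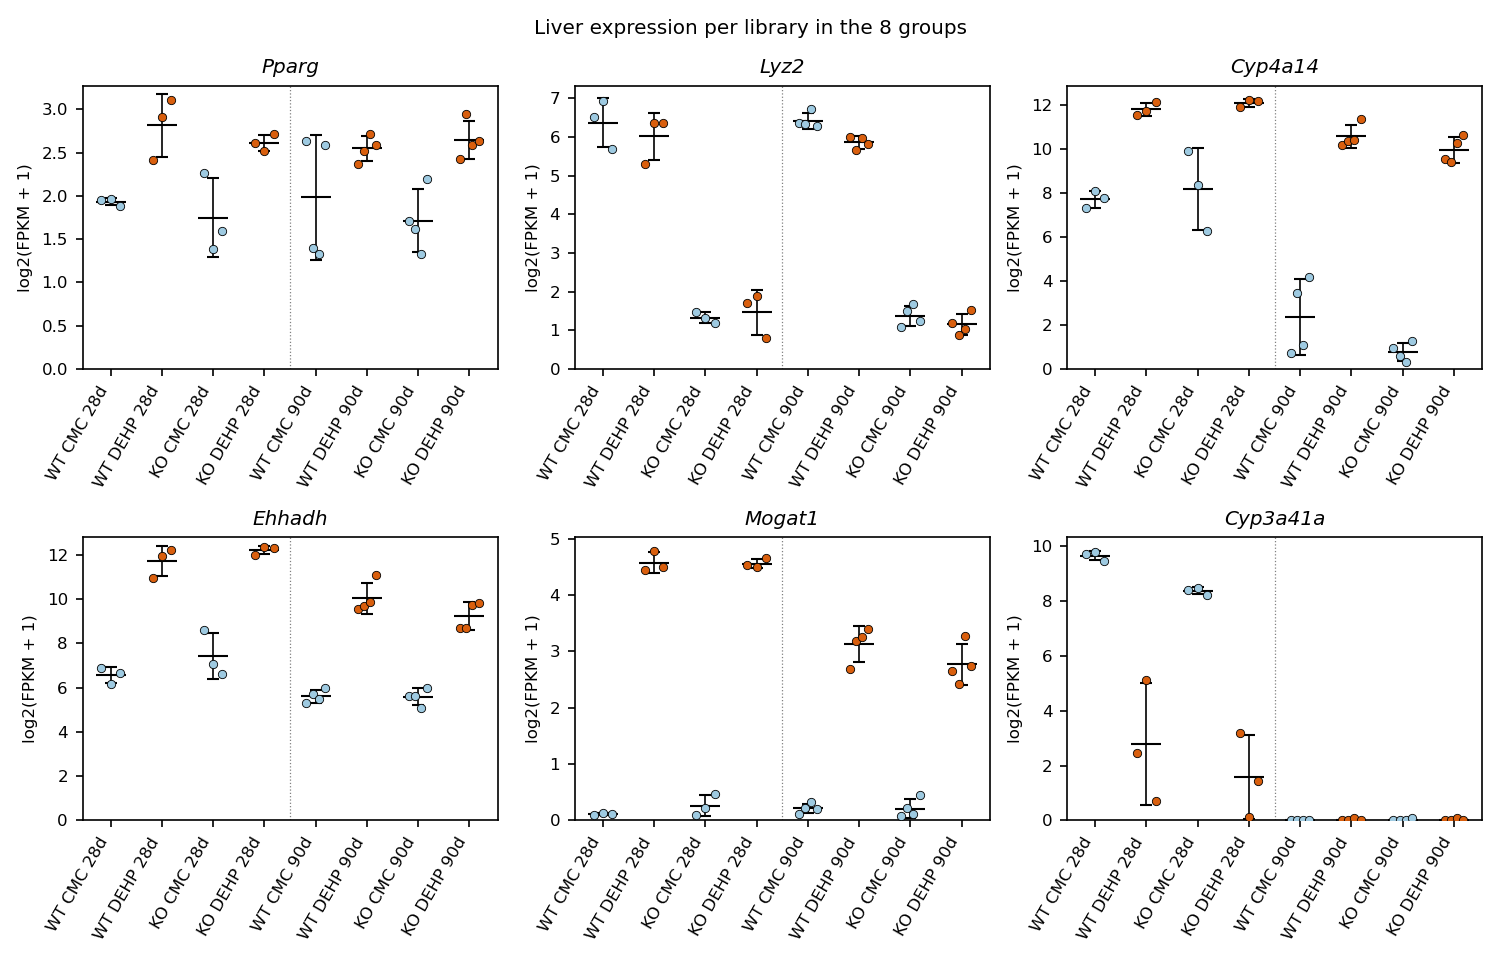
log2(FPKM + 1) of Pparg, Lyz2, Cyp4a14, Ehhadh, Mogat1 and Cyp3a41a in each of the 28 libraries by group, with the group mean and SD. Lyz2 is near the floor in every knockout group, and Ehhadh and Mogat1 are higher under DEHP in each genotype and at each time.

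The genotype by DEHP interaction at 90 days called 0 genes in limma, with 653 genes at an unadjusted p under 0.05. The smallest p-values belonged to Coq10a, a coenzyme Q binding protein gene (log2 0.78, SE 0.135, adjusted p = 0.0632), Clec3b (2.27, adjusted p = 0.0845), Sh3yl1 (0.70, adjusted p = 0.232), Lyz1 (1.26, adjusted p = 0.244) and Sgf29 (0.75, adjusted p = 0.36). With a pseudocount of 1, the pancreas list had a median log2 difference of 7.55 (13 higher and 0 lower when adjusted within the list). Camera put the list higher (adjusted p = 7.0e-13, and 0.639 with an estimated correlation). At 90 days 3 knockout DEHP libraries, 1 wild-type DEHP library and 1 wild-type CMC library held its transcripts at high levels. The adipocyte list had a median of 0.68 and the endothelial list -0.11. Fatty acid oxidation genes had a median of -0.17 and 0 calls of 47 (lower by camera, adjusted p = 0.00399, and 0.819 with an estimated correlation). Without the 5 libraries 30 genes were called, 29 higher, led by Ins2, Ctrc, Ins1 and Clps, which are pancreas genes and were named after their values were seen. These calls rest on KO DEHP replicate 4, the 1 library left in its group, assumed to vary like the others, and its pancreas score of 1.69 was the highest of the 23 left. Of the genes called in wild type, 249 of 556 higher and 44 of 206 lower were called the same way in the knockout, where independent lists would share 24.8 and 2.42, and 1 was called the opposite way. Pearson's r across the 11213 genes was 0.472, genes being no independent replicates. On simulated changes at this interaction the fit recovered 49.3% of 1.5-fold and 86.6% of 2-fold changes.

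Whether the difference under DEHP changed between 28 and 90 days was tested over the mean of both genotypes. Sex as read from the transcripts differs between these times, so the test is of time and sex together. Cyp4a12a had a log2 difference of 6.89 and 6.93 at 28 days in wild type and knockout, and of 1.73 and 1.5 at 90 days, a change of -5.29 (SE 0.162, adjusted p = 9.0e-18). Cyp4a12b changed by -4.14, the gene being listed at 0 in wild type under CMC at 28 days, Cyp3a44 by 4.43 and the transporter gene Slc22a26 by 3.35. In all, 560 genes had a higher and 541 a lower difference at 90 days. Of 22 female-biased genes, 12 were higher and 1 lower (16 higher and 2 lower when adjusted within the list; higher by camera with adjusted p = 1.4e-17, and adjusted p = 0.00344 with an estimated correlation). Of 18 male-biased genes 4 were higher and 4 lower (4 and 5 when adjusted within the list, not passing by camera, adjusted p = 0.0891). Fatty acid oxidation genes had 3 higher and 23 lower of 47 (3 and 26 when adjusted within the list). By camera the list lay lower (adjusted p = 2.1e-17, and 0.326 with an estimated correlation). Acaa1a and Acot2 rose less at 90 days, with changes of -1.09 and -2.10, whereas Cyp4a14 and Cyp4a10 rose more, by 4.71 and 2.62. Under CMC Cyp4a14 had 217 ± 55.9 FPKM in wild type at 28 days and 7.27 ± 7.96 at 90 days. Periportal genes had 8 higher and 0 lower of 14 (10 and 0 when adjusted within the list). They lay higher by camera (adjusted p = 2.8e-08, and 0.00631 with an estimated correlation). Interferon-stimulated genes had 9 higher and 0 lower of 27 (11 and 0 when adjusted within the list). Camera placed them higher (adjusted p = 5.1e-08, and 0.326 with an estimated correlation). Of fatty acid synthesis genes 1 was higher and 11 were lower of 23 (2 and 14 when adjusted within the list). As a list these genes lay lower by camera (adjusted p = 9.0e-08, and 0.326 with an estimated correlation). Of 21 NRF2 genes 0 were higher and 8 lower (0 and 12 when adjusted within the list). Camera placed these lower (adjusted p = 5.1e-08, and 0.305 with an estimated correlation). The pancreas list had a median of 4.07, the adipocyte list 0.74 and the endothelial list -0.073. Of genes higher under DEHP at 28 days in wild type, 401 of 1158 were also called higher at 90 days, with 57.4 by independent lists, and 280 of 1301 in the knockout, with 58.1. Opposite calls numbered 3 and 7. In all 4 DEHP comparisons 223 genes were called, 195 higher and 28 lower in each. Library weights gave 1807 genes for the change between times in place of 1101.

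**Figure D3:**
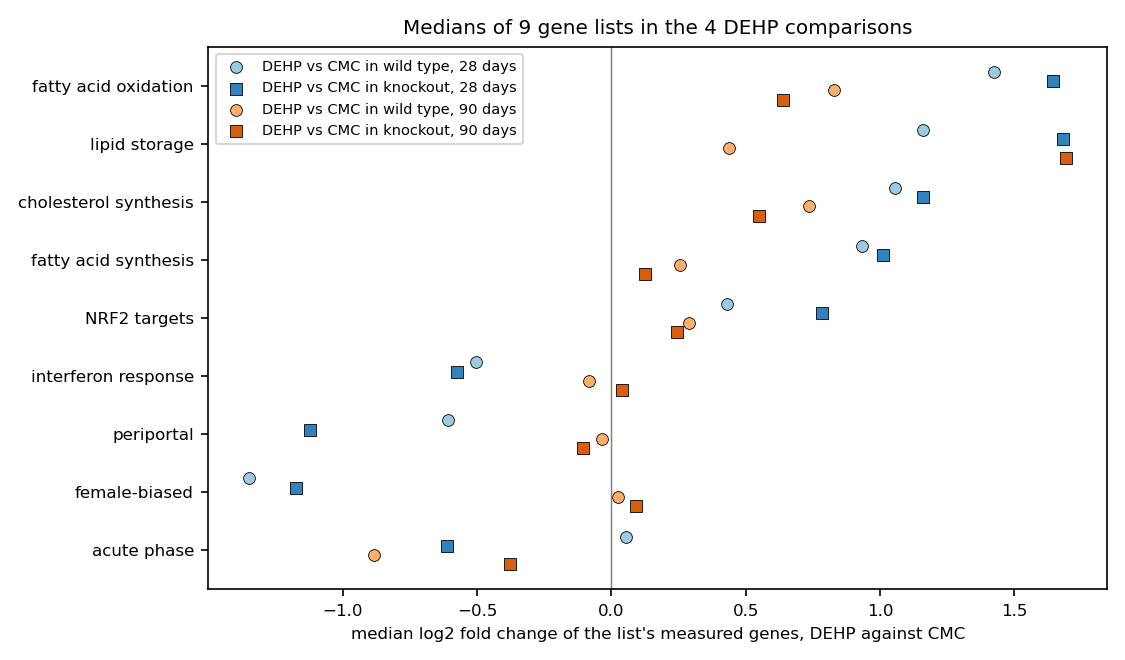
Median log2 fold change, DEHP against CMC, of 9 fixed gene lists in wild type and knockout at 28 and 90 days. Fatty acid oxidation and PPARgamma lipid storage genes lie above 0 in all 4 comparisons, and the libraries of 28 and 90 days also differ in Xist and Y-linked transcripts.

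Knockout was then compared with wild type within each agent and time. Under CMC at 28 days 5 genes passed, all lower in the knockout. Lyz2 had 1.51 ± 0.235 against 86.9 ± 35.1 FPKM (SD, n = 3; log2 fold change of -5.05, SE 0.29, adjusted p = 3.8e-11), and its neighbour Lyz1, whose reads may be shared with Lyz2, had 0.563 ± 0.232 against 3.56 ± 0.63 FPKM (-1.55, adjusted p = 7.4e-04). The others were the female-biased cytochrome genes Cyp3a16 (2.89 ± 2.14 against 18.2 ± 6.96 FPKM; -2.42, adjusted p = 4.3e-05), Cyp3a41b (-1.63, adjusted p = 2.7e-08) and Cyp3a44 (-1.06, adjusted p = 0.00858). Of 22 female-biased genes, 0 rose and 3 fell (1 and 6 when adjusted within the list). They lay lower by camera (adjusted p = 2.2e-18, 0.00268 with an estimated correlation and 0.0183 by fry). Endothelial markers had a median of 0.46 and 0 calls of 15 (higher by camera with adjusted p = 2.1e-04, and adjusted p = 0.923 with an estimated correlation), with WT CMC replicate 7 low in them. The call of Cyp3a44 was lost without KO CMC replicate 6 or WT CMC replicate 6, 8 genes passed without KO CMC replicate 7, and the 3 Cyp3a calls were lost with a pseudocount of 0.1. The stricter filter called 2, the fit of the same time point 3 and a fit of these 2 groups alone 1.

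Under DEHP at 28 days 2 genes passed, Lyz2 (1.89 ± 1.02 against 67.3 ± 24.95 FPKM, SD, n = 3; log2 fold change of -4.56, SE 0.29, adjusted p = 3.8e-10) and Lyz1 (0.597 ± 0.17 against 2.81 ± 0.714 FPKM; -1.24, adjusted p = 0.0434). Gsr, glutathione reductase, Tm4sf4 and Cct7 came next, at log2 0.55, -0.57 and 0.48, and did not pass. Periportal genes had 0 calls of 14 with a median of -0.34 (0 higher and 2 lower when adjusted within the list). The list lay lower by camera (adjusted p = 1.6e-09, 0.00535 with an estimated correlation and 0.04 by fry). Fatty acid oxidation genes had 0 calls of 47 with a median of 0.31 (higher by camera, adjusted p = 8.5e-06, 0.972 with an estimated correlation and 0.955 by fry). Acute phase genes had a median of -0.63 (lower by camera, adjusted p = 1.5e-10, 0.837 with an estimated correlation and 0.955 by fry). WT DEHP replicate 5 had a mean log2 value of 9.18 on that list, and it lay between 7.12 and 7.28 in the other wild-type DEHP libraries. The same library was low in endothelial markers, whose median was 0.42. The call of Lyz1 was lost in 5 of 6 omissions of 1 library, all but WT DEHP replicate 7. A fit of these 2 groups alone called 0 genes and library weights 218, with 146 higher and 72 lower. The stricter filter, the replicate block, the fit of the same time point and the omission of the 3 libraries low in endothelial markers each called 1.

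Under CMC at 90 days Lyz2 alone passed (1.62 ± 0.482 against 85.3 ± 12.9 FPKM, SD, n = 4; log2 fold change of -5.05, SE 0.251, adjusted p = 1.5e-12). Plpp5, Zbtb16, St5 and Slc45a3 came next, at log2 -0.89, -1.34, -0.58 and -0.75 (adjusted p = 0.159 for each), and did not pass. Of 18 clock genes 0 passed over all genes (6 higher and 2 lower when adjusted within the list). They lay higher by camera (adjusted p = 0.00141, 0.556 with an estimated correlation and 0.206 by fry). The pancreas list had a median of -2.37 (lower by camera with adjusted p = 2.9e-04, and adjusted p = 0.636 with an estimated correlation). WT CMC replicate 4 held those transcripts. The adipocyte list had a median of -0.41 and the endothelial list 0.028. The count was 5 without WT CMC replicate 1, where St5 and Slc45a3 passed, and 2 without KO CMC replicate 4. The pancreas covariate gave 3, and a fit of these 2 groups alone and the omission of the 5 libraries with pancreas transcripts 2 each.

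Under DEHP at 90 days 57 genes passed, 39 higher and 18 lower in the knockout. Lyz2 fell to 1.25 ± 0.454 against 57.2 ± 6.32 FPKM (SD, n = 4; log2 fold change of -4.70, SE 0.251, adjusted p = 7.3e-12). Wdfy1 (Entrez 69368, chromosome 1, 79702262 to 79776143), a gene of endosomal Toll-like receptor signalling, had 6.62 ± 0.964 against 1.40 ± 0.494 FPKM (1.68, adjusted p = 0.00309). Ppp1r3b, a glycogen-targeting phosphatase subunit, and Gys2, the liver glycogen synthase, had 17.1 ± 1.12 against 46.7 ± 7.14 FPKM and 50.5 ± 8.44 against 30.7 ± 1.31 FPKM. Of 18 clock genes 2 rose and 1 fell (6 higher and 1 lower when adjusted within the list; not passing by camera, adjusted p = 0.0525), with Per3 at 0.89, Tef at 0.67 and Arntl at -0.86. The clock list passed as higher with the pancreas score as a covariate (adjusted p = 0.0283) and after upper quartile scaling or quantile normalization (adjusted p = 0.0207 and 0.0121), but not with the replicate block (adjusted p = 0.0692). Upp2, Plekhg5, Ngef and Gadd45a rose by 0.75, 0.70, 0.77 and 0.86, and Zbtb16, Tsc22d3, Tubb2a and Ddc had log2 fold changes of -1.40, -1.23, -1.09 and -1.03. Of 23 fatty acid synthesis genes 0 rose and 2 fell, Lpin1 (-1.0) and Agpat2 (-0.46). Fatty acid oxidation genes had 0 calls of 47 and a median of -0.21 (lower by camera, adjusted p = 3.6e-08, 0.906 with an estimated correlation and 0.767 by fry). Sterol synthesis genes had 0 calls of 25 and a median of -0.27 (lower by camera, adjusted p = 5.9e-06, 0.906 with an estimated correlation and 0.767 by fry). In 53 genes the groups did not overlap (1 in 35 unselected genes by chance). The pancreas list had a median of 5.11 (13 higher and 0 lower when adjusted within the list; higher by camera with adjusted p = 5.4e-07, and adjusted p = 0.906 with an estimated correlation). The adipocyte list had a median of 0.36 and the endothelial list -0.083. Of the 17 genes named by rule and called, 5 kept the call in every omission of 1 library, and 17 genes in all were called with the pancreas score as a covariate. Without the 5 libraries with pancreas transcripts 51 were called, 6 of them among the 57, with KO DEHP replicate 4 alone in its group, assumed to vary like the others. That library is low in endothelial markers and has the highest pancreas score of those left. A fit of these 2 groups alone called 10, the replicate block and no filter 31 each, the fit of the same time point 36, library weights 120 and the omission of the 3 libraries low in endothelial markers 20. The count was 21, 26, 20 and 16 without KO DEHP replicates 1, 2, 3 and 4, and 19, 28 and 109 without WT DEHP replicates 2, 3 and 4, and the higher share of 68.4% became 44.8% after upper quartile scaling and 33.3% after quantile normalization.

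Over the mean of the 4 agent and time strata, 30 genes were higher and 14 lower in the knockout. Lyz2 gave -4.84 (SE 0.135, adjusted p = 2.2e-18), Lyz1 -0.81 (adjusted p = 1.4e-04), Wdfy1 1.09 (adjusted p = 1.4e-04) and Cyp3a41b -0.41 (adjusted p = 0.00158). The Cyp3a41b value came almost wholly from 1 stratum, CMC at 28 days, where the difference was -1.63. Cyp3a16 likewise had -0.64 over the mean and -2.42 in that stratum. Clock genes moved in opposite ways: Tef, Dbp and Per3, outputs and repressors of the clock, were higher by 0.54, 1.04 and 0.55, and Arntl, its activator, had a log2 difference of -0.44. Of 18 clock genes 3 rose and 1 fell (10 and 3 when adjusted within the list). They lay higher by camera (adjusted p = 0.0156, 0.5 with an estimated correlation and 0.0275 by fry). The hour of collection was not given. Unfolded protein and stress response genes had 0 calls of 20 with a median of -0.13 (lower by camera, adjusted p = 1.2e-07, 0.0321 with an estimated correlation and 0.257 by fry). Female-biased genes had 2 lower of 22 (1 higher and 6 lower when adjusted within the list). They lay lower by camera (adjusted p = 3.0e-10, 0.0321 with an estimated correlation and 0.115 by fry). Monocyte and macrophage markers had Lyz2 alone lower of 10, with a median of 0.10 and a mean of -0.38 that Lyz2 carries. Kupffer cell markers had 0 calls of 14 and a median of 0.25 (higher by camera, adjusted p = 0.0069, 0.764 with an estimated correlation and 0.486 by fry). WT CMC 28-day replicate 7 and WT DEHP 28-day replicate 5 were low on that list, at mean log2 values of 3.74 and 3.47 with 4.45 as the lowest of the other wild-type libraries of 28 days, which raises the difference. At 90 days its medians were 0.093 under CMC and 0.24 under DEHP, neither passing by camera, although under DEHP the list passed as higher with the pancreas score as a covariate (adjusted p = 0.00211). Without the 3 libraries low in endothelial markers 15 genes passed. Library weights gave 153, the stricter filter 23, the replicate block 25 and no filter 26. The count was 18 without WT DEHP 28-day replicate 5, 24 without WT CMC 28-day replicate 5, 25 and 29 without KO CMC 28-day replicates 7 and 6, 26 and 29 without KO CMC 90-day replicates 3 and 2, and 27 without WT DEHP 90-day replicate 2. The higher share of 68.2% became 53.3% after upper quartile scaling and 41.7% after quantile normalization.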

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

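The tests of sex, pancreas tissue, macrophage number and gene positions were chosen after the results were seen, and the counts of other splits of the libraries were planned. A first search asked for a library far from the other 3 of its group at 90 days. Of 163 pairs of gene and group, 16 had one, where chance gives about 1 in 20, or 8.15. WT DEHP replicate 4 supplied 7 of them, and it also holds pancreas transcripts: Cyp4a14 at 2663.7 FPKM (others 1173.7 to 1372.6), Cyp4a10 at 2166.3 (892.1 to 1086.3), Cyp4a31 at 80.21 (40.99 to 42.54), Ehhadh at 2175.0 (751.1 to 937.1), Acot1 at 222.52 (47.87 to 62.51), Aldh1a1 at 1301.7 (771.2 to 840.5) and Hacl1 at 180.29 (123.2 to 131.8). Without this library every one of these genes kept its call in wild type at 90 days. WT CMC replicate 2 had Serpina12 at 15.08 FPKM (others 18.95 to 19.53) and Apoa4 at 133.25 (77.05 to 84.72). WT CMC replicate 3 had Gstm4 at 15.35 (25.32 to 26.69), Tkt at 26.41 (29.55 to 29.86) and Lyz2 at 104.51 (76.73 to 80.55), and WT CMC replicate 4 had Elovl5 at 73.8 (42.98 to 43.98). WT DEHP replicate 1 had Ddc at 56.65 (31.22 to 35.43). In the knockout, CMC replicate 4 had Serpina1e at 6106.2 (9934.9 to 10146.0) and DEHP replicate 2 had Apoa4 at 63.34 (13.68 to 17.66).

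A second search asked where the difference under DEHP differed between groups. Between genotypes at 28 days 2 genes passed, Cyp3a41b (log2 1.61) and Cyp3a16 (2.30). These are about their CMC gaps (-1.63 and -2.42), so a changed response is not shown. Between 28 and 90 days 1101 did, among them Cyp4a12a at -5.29, Cyp3a44 at 4.43, Slc22a26 at 3.35 and Cyp4a12b at -4.14. All 4 but Slc22a26 are on sex-biased lists, whose CMC levels, like sex transcripts, differ between the times.

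The first pattern weighed is that the 12 libraries of 28 days hold Xist and no Y-linked transcripts while every label says male. A scaling of values that differs between times is argued against, since the median of all tested genes moved by 0.10018 on the log2 scale from 90 to 28 days under CMC while Xist moved by 5.1986. Female mice at 28 days may be the source: the female-biased list lay 5.2769 higher at 28 days, with 22 of 22 genes called higher, and the male-biased list had a change of -3.4199, with 18 of 18 called lower. Whether the labels or the samples are in error stays open, and sex and time cannot be told apart in any comparison across times. Sex as a modifier of the difference under DEHP was not tested, since each time holds 1 sex by these transcripts.

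The second pattern is the pancreas transcripts of 5 libraries of 90 days, KO DEHP replicates 1, 2 and 3, WT DEHP replicate 4 and WT CMC replicate 4, with scores from 9.1653 to 11.172 against at most 1.6902 in the other 23. An effect of DEHP in the knockout as the whole cause is argued against by the score of 9.7773 in a wild-type library under CMC. Pancreas tissue carried into the sample is a candidate explanation, since the pancreas genes kept near 1 ratio to each other in the 5 libraries, with a median SD of 0.11214 about the library mean while those means ranged over 2.0066, and Ctrb1 lay between 1829 and 7438 FPKM in them and at most 4.98 elsewhere. The transcripts were in 3 of 4 knockout DEHP libraries and 2 of 12 others at 90 days (Fisher's exact test, two-sided, p = 0.0632), so a share of the knockout result at 90 days moves with them. The adipocyte list still passed as higher in that comparison with the pancreas score as a covariate (adjusted p = 0.033, 5.9e-05 without the covariate and 0.224 with an estimated correlation), but not in the interaction at 90 days (0.37, 0.00138 and 0.639 in that order), and its call as lower in the knockout under CMC at 90 days was lost (0.124, 0.016 and 0.636).

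The third pattern is the genotype difference itself, with Lyz2 at -4.8388 over the 4 strata. Fewer macrophages in the knockout are argued against, since 22 other macrophage markers had a median of 0.22347, from -0.178 to 0.504, and 0 were called by limma, although 2 wild-type libraries of 28 days low in Kupffer cell markers raise these values (at 90 days the Kupffer cell list had medians of 0.093 under CMC and 0.24 under DEHP). The 44 called genes lie near each other more than random genes do, 21 of them within 5 Mb of another, against a median of 9 and a highest of 24 in 10000 draws (permutation p = 0.0026997). Neighbours regulated together may account for it, since as many genes of smallest p from the DEHP comparisons had up to 18 with a neighbour. A change at the Lyz2 locus made in breeding the knockout was not tested, the construct not being given in the sources used here.

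Other splits of the same libraries were counted. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. At 28 days 1 of the 10 gave as many genes for DEHP in wild type (1850, highest other 618) and 1 for DEHP in the knockout (2284, highest other 3). For knockout against wild type it was 1 under CMC (5, highest other 2) and 2 under DEHP (2, highest other 7). At 90 days 1 of the 35 splits gave as many for DEHP in wild type (762, highest other 107) and 1 for DEHP in the knockout (633, highest other 3), so chance was excluded. The share was not under 0.05 for knockout under DEHP (2 of the 35 splits, 57 genes, highest other 67). Under CMC 7 of the 35 splits gave as many genes as the knockout (1, highest other 26), but a count of 1 is equalled by any single call, and the 1 gene was Lyz2 (-5.05, adjusted p = 1.5e-12), about as low in all 4 strata. Of 100 regroupings, 16 gave as many genes for the interaction at 28 days (2, highest other 6), so chance was not excluded. At 90 days the interaction called 0 genes, which 100 of the 100 must equal (highest other 6), so nothing was tested. For DEHP by time the share was under 0.05 (1 of the 100, the real grouping, 1101 genes, highest other 30). For the mean genotype difference the share was under 0.05 in the reported fit alone (1 of the 100, 44 genes, highest other 40). That count of 44 fell to 18 without WT DEHP 28-day replicate 5. Other settings gave fewer or more genes and were not regrouped. In wild type at 28 days the splits of 618, 589, 48 and 8 genes put both libraries low in endothelial markers on 1 side, and the other splits that part them gave 0 to 3, so the count varies widely even with both on 1 side. The split of 67 genes put the 4 DEHP libraries with pancreas transcripts on 1 side. The split of 26 genes set KO CMC replicate 1 with WT CMC replicates 1, 2 and 3. In wild type at 90 days, the other splits that part all 4 replicate numbers gave 0 or 1 genes, but 8 are too few for a share under 0.05.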

How the results depend on the processing

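The pancreas covariate, both omissions of several libraries and the block in a fit of 2 groups were chosen after the data were seen, and the other alternatives were planned. Unless said otherwise the cause of a moved value was not tested. Counts of called genes under DEHP at 28 days in the knockout stayed within 1.5 times under every alternative run. For the genes named by rule, leaving out 1 library kept direction and side of the threshold in 1385 gene and omission pairs, 139 were no longer called, 5 were newly called and 1 reversed; upper quartile scaling kept 175 of 177 and quantile normalization 172. No scaling moved the median of all genes by over 0.1.

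With a pseudocount of 0.1 the knockout under CMC at 28 days had 2 genes and the interaction at 28 days 0. With no filter (17792 genes tested) the knockout under DEHP at 90 days had 31 and the mean genotype difference 26. With the stricter filter (7018 genes tested) the knockout at 28 days had 2 under CMC and 1 under DEHP, the interaction at 28 days 0 and the mean genotype difference 23. With library weights DEHP in wild type at 28 days had 3184, the knockout under DEHP 218 at 28 days and 120 at 90 days, DEHP by time 1807 and the mean genotype difference 153. With the replicate block the knockout under DEHP had 1 at 28 days and 31 at 90 days, the interaction at 28 days 1 and the mean genotype difference 25, while DEHP in wild type at 90 days had 756. In the fit of the same time point the knockout at 28 days had 3 under CMC and 1 under DEHP, the interaction at 28 days 0, and the knockout under DEHP at 90 days 36.

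In the fit of the 2 groups compared, with fewer libraries behind each variance, DEHP in wild type had 926 at 28 days and 304 at 90 days (298 with the replicate block), DEHP in the knockout at 90 days 361, and the knockout 1 under CMC and 0 under DEHP at 28 days and 2 and 10 at 90 days. With the pancreas score as a covariate DEHP in the knockout at 90 days had 57, the knockout at 90 days 3 under CMC and 17 under DEHP, and the interaction at 28 days 1. Prss2, on which the score is built, turned to -0.22939 in the knockout under DEHP at 90 days, and the Pparg difference between genotypes under DEHP at 90 days, 0.10 as reported and not called, turned to -0.053168. Without the 5 libraries with pancreas transcripts DEHP at 90 days had 484 in wild type and 272 in the knockout, the knockout under CMC at 90 days 2, the interaction 1 at 28 days and 30 at 90 days. The knockout under DEHP at 90 days, with 1 library left, then had 51, of which 6 were among the 57, and the mean genotype difference 41, of which 17 were among the 44. Without the 3 libraries low in endothelial markers the knockout under DEHP had 1 at 28 days and 20 at 90 days, and the mean genotype difference 15. Of 55 list calls by camera in the DEHP comparisons, 3 held with an estimated correlation, 52 calls were made after either scaling, 56 with the block and 50 with the pancreas covariate. Over all 12 comparisons that covariate ended 22 list calls and added 17, and an estimated correlation ended 121; not all of these lists are described.

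Leaving out 1 library gave these ranges of counts. DEHP in wild type ran from 1415 to 1914 at 28 days and from 379 to 893 at 90 days, and DEHP in the knockout from 1712 to 2080 and from 253 to 540. The knockout under CMC ran from 4 to 8 and from 1 to 5, and under DEHP from 1 to 3 and from 16 to 109. The interaction ran from 1 to 3 at 28 days and from 0 to 2 at 90 days, DEHP by time from 929 to 1216 and the mean genotype difference from 18 to 66. Coq10a passed in the interaction at 90 days without WT CMC replicate 1 or WT DEHP replicate 3, and Clec3b without the latter. The Pparg difference between genotypes under DEHP at 90 days ran from -0.0022551 without KO DEHP replicate 2 to 0.17043 without KO DEHP replicate 1. A gene of 1 kb at 1 FPKM rests on as few as 9.2 fragments, and recovery of simulated changes was not broken down by expression level.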

Other observations

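Pathway terms that the deposited table carries for 6062 tested genes were chosen for a test after the data were seen (hypergeometric, adjusted over 319 terms within a comparison and direction, genes not being independent). Proteasome subunits were higher under DEHP at 28 days, 34 of 48 in wild type (5.71 by chance, adjusted p = 1.3e-19) and 35 of 48 in the knockout (adjusted p = 5.0e-19). In the DEHP by time test 28 of 48 were lower at 90 days (adjusted p = 2.2e-20), times that also differ in sex transcripts. Genes of oxidative phosphorylation were higher at 28 days, 57 of 119 in wild type and 64 of 119 in the knockout, and 40 of 119 were higher in wild type at 90 days (adjusted p = 1.4e-20, 1.1e-23 and 2.7e-18). Ribosomal protein genes were higher in the knockout at 28 days (59 of 161, adjusted p = 1.1e-12). Complement and coagulation genes, which hepatocytes secrete, were lower in all 4 DEHP comparisons: 47 of 110 and 55 of 110 at 28 days in wild type and knockout, then 31 of 110 and 14 of 110 at 90 days (adjusted p from 1.2e-25 to 4.6e-08). The last count stands beside pancreas transcripts, and with the pancreas score as a covariate 11 genes in all were lower in that comparison. Enzymes that break down branched-chain amino acids were higher, 28 of 56 in wild type at 28 days, 26 of 56 at 90 days and 30 of 56 in the knockout at 90 days (adjusted p = 6.1e-11, 7.4e-16 and 1.4e-21), the last beside pancreas transcripts.

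Fixed lists on glucose and growth hormone add to this. Of 24 genes of glucose metabolism and insulin signalling, 1 rose and 6 fell in wild type at 28 days (1 higher and 8 lower when adjusted within the list), with G6pc at -1.71, Fbp1 at -0.75, Slc2a2 at -0.75 and Pygl at -0.54, and Pfkfb1 at 0.62. Camera put the list lower (adjusted p = 0.00319, and adjusted p = 0.342 with an estimated correlation). In the knockout 1 rose and 7 fell (2 higher and 8 lower when adjusted within the list; lower by camera with adjusted p = 0.0223, and adjusted p = 0.506 with an estimated correlation). Of 17 growth hormone and JAK-STAT genes, 0 rose and 3 fell in wild type (0 higher and 3 lower when adjusted within the list), with Igf1 at -1.58, Igfals at -1.73 and Ghr at -0.83. By camera the list lay lower (adjusted p = 0.0186, and adjusted p = 0.342 with an estimated correlation). In the knockout 0 rose and 4 fell, the same 3 and Stat5b at -0.51 (0 higher and 4 lower when adjusted within the list). As a list these genes lay lower by camera (adjusted p = 0.00686, and adjusted p = 0.351 with an estimated correlation). Bile acid genes went both ways, with 2 higher and 6 lower of 21 in wild type at 28 days (3 higher and 6 lower when adjusted within the list; not passing by camera, adjusted p = 0.3). In the knockout 3 were higher and 8 lower (3 higher and 8 lower when adjusted within the list; not passing by camera, adjusted p = 0.226). In the knockout at 90 days the heat shock list had 0 higher and 2 lower of 17, Hspa1a at -0.76 and Hspa1b at -1.52 (0 higher and 3 lower when adjusted within the list), beside pancreas transcripts in 3 of its libraries. The list lay lower by camera (adjusted p = 1.3e-04, and adjusted p = 0.47 with an estimated correlation).

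Of the clock genes, Arntl had 9.04 ± 0.516 FPKM in wild type and 10.5 ± 1.42 in the knockout under CMC at 28 days (SD, n = 3), and 2.02 ± 0.816 and 1.02 ± 0.393 at 90 days (SD, n = 4). Dbp had 1.83 ± 0.951 and 3.54 ± 1.15 FPKM at 28 days, and 33.1 ± 12.3 and 64.1 ± 10.5 at 90 days. Under DEHP at 28 days Arntl had 6.78 ± 2.14 and 4.31 ± 1.15 FPKM and Dbp 8.41 ± 8.01 and 16.5 ± 1.5 in wild type and knockout, and at 90 days Arntl had 2.76 ± 0.226 and 1.08 ± 0.198 and Dbp 30.6 ± 3.54 and 75.5 ± 15.1. The hour of collection was not given, the times also differ in sex transcripts, and the difference between times was not tested.

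Single libraries stood apart in other ways. The mean log2 value of the sinusoidal endothelial list was 2.5885 in WT CMC 28-day replicate 7, 2.1984 in WT DEHP 28-day replicate 5 and 2.5957 in KO DEHP 90-day replicate 4, with 3.1472 as the lowest of the others. The acute phase list ranged from 6.73 to 9.43 among WT CMC libraries of 90 days and from 6.92 to 9.18 among KO CMC libraries of 90 days.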
